A study of Danio rerio with 8 samples.

How the data were processed

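Fluorescence-sorted pineal complex cells from zebrafish embryos of 24 to 26 hours post-fertilization were profiled by RNA sequencing in 8 libraries, 4 from uninjected wild-type and 4 from embryos injected with a tbx2b splice morpholino. Per the labels, the libraries form 4 pairs of technical replicates. Per the submitters' processing notes, CASAVA 1.8.2, FastQC 0.10.0, Trimmomatic 0.32, Bowtie2, TopHat2 and Cuffdiff were used with the Zv9 build; their settings, the gene annotation and the handling of the technical replicates are not given in the sources used here. The authors' table has 32433 rows, 1 per gene, with the locus, a test status, and 1 FPKM value (fragments scaled by transcript length and by the number of mapped fragments) per group, per the file headers. The deposited log2 fold change sets the knockdown over the wild-type, and the deposited p value and q value come from the authors' test, per the file headers. FPKM divides by gene length and library total, so values can be compared between groups for a gene but depend on the other RNAs sampled. Group values carry no library totals, so depth, counting intervals and detection limits could not be given. Coordinates are those of the file on Zv9; the base from which starts are counted is not given in the sources used here, and a locus can be a merged region shared by overlapping genes, which holds for 7018 rows.

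The status column marks 18954 genes as tested, 13360 as not tested, 112 as having too little data and 7 as having too much. The last group, listed at 0, holds hsp70.1, hsp70.2, hsp70.3, hsp70l, atp2a1, eef1a1l1 and zgc:162612, so a 0 for these is not a measurement. The deposited q was checked against a Benjamini-Hochberg adjustment of the deposited p over all tested genes and differed by at most 5.2e-07. The smallest deposited p is 5e-05, shared by 54 genes, which puts the smallest q at 0.0176. Genes at 1 FPKM or more in both groups numbered 15109; their median log2 fold change was -0.02. Rescaling each group to TPM would add 0.106 to every log2 fold change, because the FPKM sums of the groups differ; 4 fixed list medians near 0 (parapineal, epithalamus, FGF, forebrain and midbrain) would change sign, while percentiles among random lists are unaffected by a common shift. A single RNA takes 27.5% of the FPKM sum in wild-type and 30.6% in the knockdown.

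No test across replicates could be run on group values, so calls are the authors' significance flag, described as deposited. Before the data were examined, 23 gene lists were fixed, with 744 members, of which 710 were matched, 34 of these by gene identifier through a table of current names. They cover parapineal genes, pineal photoreceptor and melatonin genes, projection neuron and early neuronal genes, epithalamus and left-right genes, the Notch, FGF, BMP and Wnt pathways, the cell cycle, innate immunity, stress and dissociation, and 11 other cell types (notochord and floor plate, erythroid, endothelial, myeloid, epidermis, neural crest and pigment, muscle, lens and retina, hatching gland and yolk layer, forebrain and midbrain, hindbrain and trunk Hox). Of the genes and lists fixed in advance, 1 gene and 1 list are not reported here, though the list is counted in the totals. The exo-rhodopsin gene of the pineal list was not matched and is not analysed here. For each list the median log2 fold change was taken over tested members above 0 in both groups. It was placed among the medians of 10000 random lists of the same size. These were drawn from 20 bins of log2(m + 0.1), where m is the mean FPKM of both groups. A list stood apart if its percentile was under 2.5 or above 97.5; this describes these libraries and is not a p value. Of the 23 lists 8 lay below and 6 above these limits, against 1.15 expected if members varied independently, like random genes. Members of a list can be co-expressed and some lists share genes, so 1.15 is not a chance rate for these lists. The deposited p values were also adjusted over each list alone, with a threshold of 0.05.

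Genes were named by a rule written in advance: tbx2b first; the 10 largest rises and 10 largest falls among called genes with 1 FPKM or more in at least 1 group, above 0 in both and with a symbol that is not a clone name; up to 6 called members of each list; up to 3 called genes per direction listed at 0 in 1 group; and, called or not, gfi1ab, sox1a, kctd12.1, kctd12.2, otx5, crx, aanat2, asmt, nr2e3, flh, isl1, elavl3, tbx2a, mdm2, cdkn1a and ccng1. Crybb1, cryba4, hbbe1.1, hbbe3, TYRP1 (2 of 2) and krt4 were chosen as examples after their values were seen, as were the genes of the 5 added lists in the closing section. The list statistic was tested on simulated data made from the 18800 genes with a fold change in this comparison. Fold changes were shuffled among genes of similar expression and lists were drawn at random. Of 100 such lists of 20 genes each, the statistic set apart 5% with no shift, 89% with a log2 shift of 0.25 and 100% with a shift of 0.5. Shuffled genes vary independently, so these rates do not hold for lists of co-expressed genes. Alternatives were a stricter q, a fold threshold, FPKM filters, pseudocounts of 1 and 0.1, centring on the median and rescaling to TPM. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.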

Results

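RNA was sequenced from cells of the zebrafish pineal complex, sorted by fluorescence from the heads of embryos at 24 to 26 hours post-fertilization. The transgenic line expresses the photoconvertible protein Kaede under regulatory sequence of flh (floating head), a homeobox gene of the pineal anlage. The pineal complex consists of the pineal organ, with its photoreceptors and projection neurons, and the left-sided parapineal organ. Of the 8 libraries, 4 came from uninjected wild-type embryos and 4 from embryos injected with a splice morpholino against tbx2b, 2 at 5 ng and 2 at 6 ng. The labels describe the libraries as pairs of technical replicates, which leaves 2 RNA samples per group. In the knockdown these 2 differ in dose, so dose and RNA sample cannot be told apart. Expression was read from the authors' deposited table, which holds 1 FPKM value per gene and group, so no spread between libraries can be given, and the depth of each library is unknown. All FPKM values below are the authors' group values, wild-type first and knockdown second, and a gene is said to have risen or fallen only where the authors' own test called it.

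The comparison asks which genes differ in pineal complex cells when Tbx2b, a T-box transcription factor needed to form the parapineal organ, is reduced. Among the genes that fell were 7 of 48 tested pineal photoreceptor and melatonin genes, 4 of 27 neural crest and pigment markers, all of which serve melanin or the melanosome, and the alpha globins hbae1 and hbae3. Of 20 tested endothelial markers 4 rose, among them the regulator etv2, as did the blood progenitor regulator tal1 and 4 contractile genes of the heart. The largest fall among called genes above 0 in both groups was that of the embryonic alpha globin hbae3, from 49.6 to 1.09 FPKM (45.6-fold). The largest rise was that of CD109, a cell surface protein that binds TGF-beta, from 0.201 to 5.92 FPKM (29.5-fold). Of 18954 tested genes, 83 were called in the authors' deposited table, of which 20 were higher and 63 lower in the knockdown.

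The targeted gene itself, tbx2b (ENSDARG00000006120, Zv9 chromosome 15, 26713281 to 26720228), was at 17.4 FPKM in wild-type and 18.3 FPKM in knockdown cells, with a q of 0.999 in the authors' deposited table. Per the labels the morpholino targets splicing. Misspliced transcripts can still be counted for the gene, so this gene-level value shows no reduction and does not check the knockdown. Its paralog tbx2a was at 8.16 and 8.43 FPKM.

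**Figure D1:**
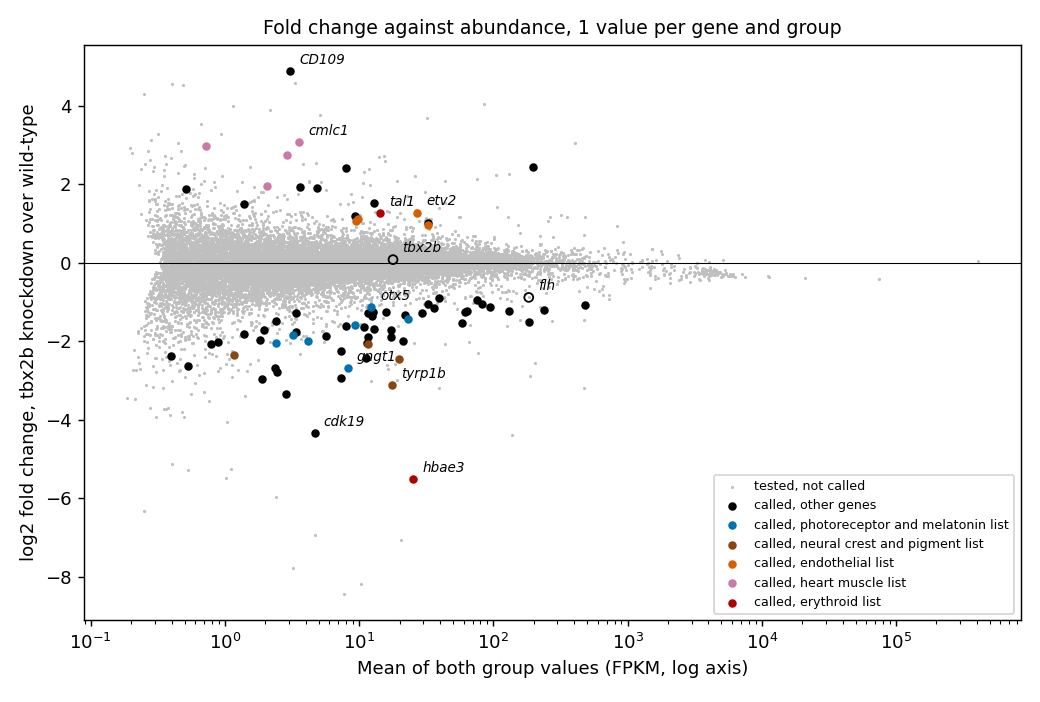
Each point is a gene tested by the authors with a value above 0 in both groups, plotted as log2 fold change (knockdown over wild-type) against the mean of both FPKM values on a log axis. Called genes are coloured by list, the heart muscle list having been chosen after the data were seen, and open circles mark named genes that were not called, among them tbx2b.

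The tested genes of the parapineal list showed no common shift. They include tbx2b itself and otx5, which stands in the pineal list as well. Of 10 tested genes in this list, 1 fell, otx5, and none rose, and adjusted over the list alone the count was again 1. The median log2 fold change was -0.01, at the 54.4 percentile of random lists matched on expression, and turned to 0.01 over members at 1 FPKM or more. Sox1a, a marker of early parapineal cells, was at 7.22 and 7.47 FPKM. The potassium channel tetramerization domain genes kctd12.1 and kctd12.2, which mark the habenular nuclei as well, were at 1.19 and 1.2 FPKM and at 4.62 and 5.81 FPKM. The parapineal marker gfi1ab was at 0.399 and 0.277 FPKM, and the authors ran no test on it. Gfi1aa, at 0.087 and 0.023 FPKM, was not tested either. The list median therefore does not cover these markers, and it does not show that parapineal genes were spared.

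Photoreceptor genes were lower as a group. Of 48 tested members of the pineal photoreceptor and melatonin list, 7 fell, none rose, and 41 were not called; 40 lay below 0. The median log2 fold change was -0.55, below the medians of all 10000 random lists (percentile 0.00), and adjusted over the list alone 14 members were lower and 1 higher. Gngt1, the gamma subunit of rod transducin, fell from 14.2 to 2.21 FPKM (6.41-fold). Both S-arrestin genes fell, saga from 3.86 to 0.934 FPKM and sagb from 6.60 to 1.65 FPKM, as did the calcium sensor recoverin (rcv1), from 4.99 to 1.39 FPKM. Gngt2a, the cone transducin gamma subunit, fell 2.98-fold and pde6g, the inhibitory subunit of the photoreceptor phosphodiesterase, fell 2.70-fold. The homeobox gene otx5 (ENSDARG00000043483, chromosome 15, 46861775 to 46867193), a regulator of circadian genes in the pineal organ, fell from 16.9 to 7.71 FPKM, with a q of 0.0287 in the authors' deposited table. The nuclear receptor nr2e3 was at 7.08 and 3.2 FPKM without passing the test (q of 0.0986 in the authors' deposited table). The related homeobox gene crx was at 9.26 and 6.82 FPKM. Aanat2, the enzyme that sets the rate of pineal melatonin synthesis, was at 3.43 and 3.13 FPKM. Asmt, the last enzyme of that pathway, was listed at 0 in both groups and not tested. Its row lies on an unplaced contig, as do those of gap43 and E2F1, also listed at 0, so this 0 may not be a measurement.

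None of the general markers of the tissue was called. The gene whose regulatory sequence drives the reporter, flh, was at 238 and 129 FPKM, a 1.85-fold difference that was not called (q of 0.0986 in the authors' deposited table). The neuronal genes isl1, at 6.86 and 7.01 FPKM, and elavl3, at 123 and 117 FPKM, differed little. None of 26 tested members of the projection neuron list was called, or passed adjusted over the list alone, and its median of 0.06 lay at the 90.2 percentile. The epithalamus and left-right list (12 tested, none called, 1 lower adjusted over the list alone) had a median of -0.08 at the 25.9 percentile, or -0.0058 over members at 1 FPKM or more. The member lower adjusted over that list alone was flh.

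Pigment genes were lower as well. Of 27 tested neural crest and pigment markers 4 fell and none rose, the median was -0.65 at the 0.00 percentile, and 10 were lower adjusted over the list alone. The called members make melanin or the melanosome: tyrp1b fell from 31.6 to 3.65 FPKM (8.67-fold), dct from 33.8 to 6.14 FPKM, oca2 from 1.95 to 0.382 FPKM and pmelb from 18.8 to 4.44 FPKM. The lens and retina list (26 tested) had 1 call, rlbp1b, a retinaldehyde-binding protein of pigment epithelium and glia, which fell from 19.0 to 3.54 FPKM. Its median was -0.87 at the 0.00 percentile, with 10 members lower adjusted over the list alone. No lens crystallin gene was called; the most abundant, crybb1, was at 17.5 and 9.55 FPKM, and cryba4 was at 10.6 and 5.93 FPKM.

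**Figure D2:**
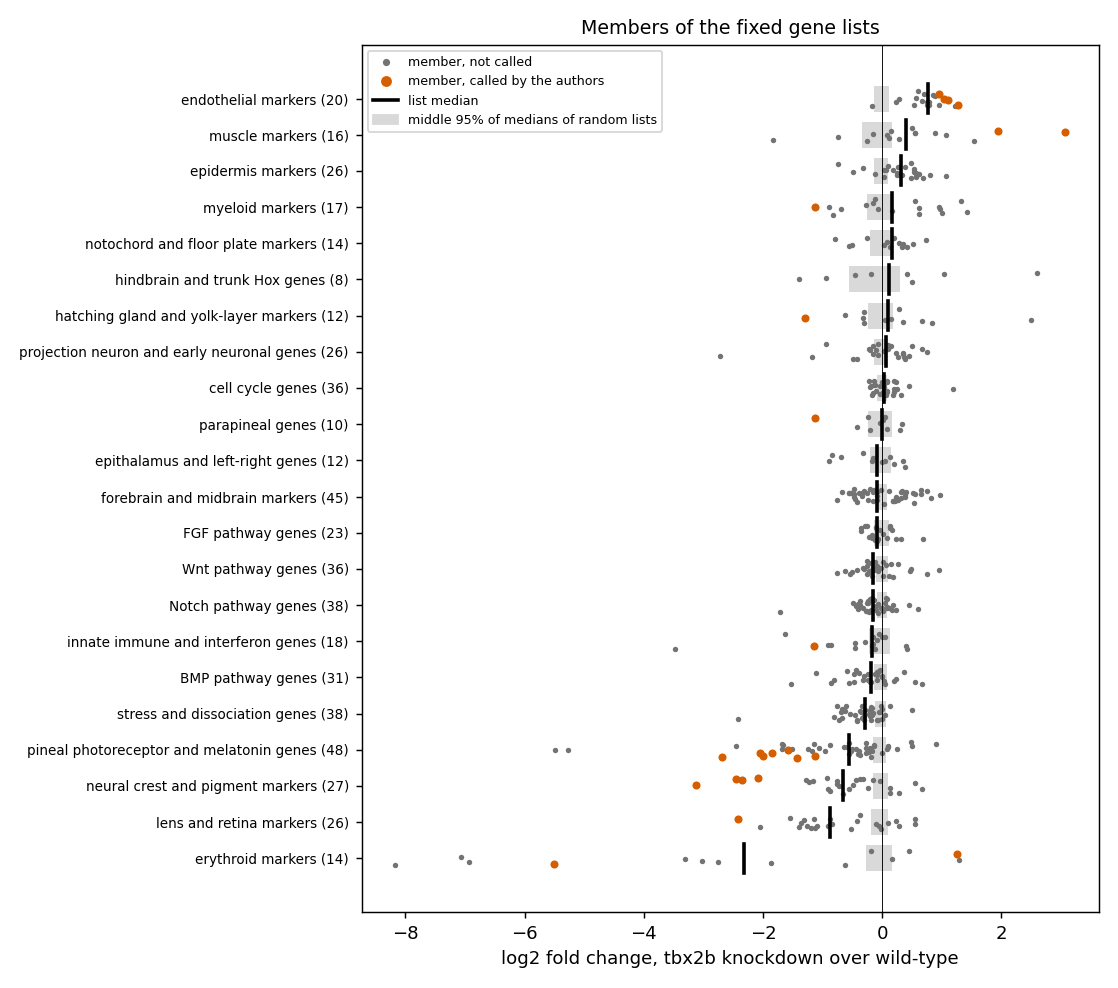
Each point is the log2 fold change (knockdown over wild-type) of a tested member of a list fixed before the data were examined, with the number of members in brackets. Orange points are genes called by the authors, black bars are list medians and grey bands hold the middle 95% of medians of random lists matched on expression; the erythroid median of -2.31 lies farthest to the left and the endothelial median of 0.77 farthest to the right.

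Markers of other cells that a sort of embryonic heads can contain moved in both directions. Of 20 tested endothelial markers 4 rose and none fell, 19 lay above 0, and 13 were higher adjusted over the list alone; the median of 0.77 lay at the 100 percentile. The risen members were etv2, the ETS factor that starts endothelial and blood fate, from 15.9 to 38.4 FPKM (2.42-fold), fli1b from 6.23 to 13.4 FPKM, the angiopoietin receptor tie2 from 6.14 to 12.7 FPKM, and clec14a from 22 to 42.7 FPKM. Tal1, which acts with etv2 in blood and vessel progenitors and stands in the erythroid list, rose from 8.48 to 20.3 FPKM. The remaining called members of the erythroid list were globins that fell: hbae3 and both copies of hbae1, listed at 3.82 and 3.44 FPKM in wild-type and at 0 in the knockdown. These copies carry the same symbol and can share reads. The erythroid list (16 tested, 14 above 0 FPKM in both groups) had a median of -2.31 at the 0.00 percentile, with 7 members lower and 2 higher adjusted over the list alone. Its members ranged widely, with quartiles of -4.96 and 0.086, and the median was -1.25 over members at 1 FPKM or more and -0.76 on log2(FPKM + 1), both still at the 0.00 percentile. The beta globin hbbe1.1 was at 20.5 and 0.0709 FPKM, with a p of 0.133 in the authors' deposited table. A further row of that name was at 9.36 and 0.0766 FPKM (p of 0.146 in the authors' test). The beta globin hbbe3 was at 40.9 and 0.304 FPKM, with a p of 0.00435 in that test, and was not called (q of 0.31).

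Of 14 tested heart muscle genes, a list chosen after the calls were seen, 4 rose, all from under 1 FPKM; without these the median log2 fold change of the list was 0.11 at the 88.5 percentile. Cmlc1, a cardiac myosin light chain, rose from 0.758 to 6.37 FPKM (8.40-fold), myl7 from 0.758 to 5.02 FPKM, the ventricular myosin heavy chain vmhc from 0.163 to 1.28 FPKM and the cardiac troponin tnnt2a from 0.840 to 3.25 FPKM. Cmlc1 and tnnt2a were the called members of the muscle list (16 tested, 2 rose, none fell; 3 higher and 1 lower adjusted over the list alone), whose median was 0.39 at the 99.99 percentile, 0.14 on log2(FPKM + 1) and 0.22 without the called members, each above the range of random lists. Epidermis markers had a median of 0.32 at the 100 percentile, with none of 26 called and none adjusted over the list alone; keratin krt4 was at 344 and 448 FPKM. Myeloid markers (17 tested) had a median of 0.17 at the 98.1 percentile, which over members at 1 FPKM or more was 0.05 at the 85.0 percentile, within the range of random lists. Their called member, the transcription factor cebpb, fell from 129.5 to 59.2 FPKM; 2 were higher and 1 lower adjusted over the list alone. The notochord and floor plate list had a median of 0.16 at the 97.61 percentile, or 0.28 over members at 1 FPKM or more, with none of 14 called by either adjustment.

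The medians of the remaining cell type lists lay within the range of random lists, though the setting changed the direction or the side of the limits for each. Hatching gland and yolk-layer markers (12 tested) had a median of 0.10 at the 85.98 percentile, which turned to -0.30 at the 0.32 percentile over members at 1 FPKM or more. Their called member rbp4l, a retinol-binding protein, fell from 16.5 to 6.74 FPKM, the 1 member that was lower adjusted over the list alone. Forebrain and midbrain markers (45 tested, none called by either adjustment) had a median of -0.08 at the 2.82 percentile, or at the 1.96 percentile on log2(FPKM + 1). Hindbrain and trunk Hox genes (8 tested, none called, 1 higher and 1 lower adjusted over the list alone) had a median of 0.12 at the 85.2 percentile, which was 0.016 on log2(FPKM + 1) and turned to -0.46 at the 4.22 percentile over the 3 members at 1 FPKM or more.

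No gene of the signalling and cell cycle lists was called. The median was -0.15 for 38 Notch pathway genes (0.12 percentile), -0.19 for 31 BMP pathway genes (0.20 percentile) and -0.15 for 36 Wnt pathway genes (0.30 percentile); rescaled to TPM the Notch and Wnt medians were -0.04 and the BMP median was -0.09. It was -0.08 for 23 FGF pathway genes (9.49 percentile, and 0.02 rescaled to TPM) and 0.03 for 36 cell cycle genes (79.9 percentile). Adjusted over the list alone, 1 BMP gene was lower and no gene of the other 4 lists passed.

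Gadd45bb, a growth arrest and DNA damage gene, fell from 41.8 to 17.1 FPKM. Cyclin G (ccng1) was at 573 and 1100.5 FPKM without passing the test (q of 0.43 in the authors' deposited table). The ubiquitin ligase gene mdm2 was at 37.6 and 52.2 FPKM, and the cell cycle inhibitor cdkn1a was at 65.6 and 52.2 FPKM; neither was called. Innate immune and interferon genes (18 tested) had a median of -0.16 at the 7.92 percentile, 4 of them lower adjusted over the list alone; socs3a, a feedback inhibitor of cytokine signalling, fell from 49.7 to 22.5 FPKM. Stress and dissociation genes had a median of -0.29 at the 0.00 percentile, with 34 of 38 below 0 and none called by either adjustment.

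Other genes with large changes belong to none of the fixed lists. Among those that fell were cdk19, a kinase of the Mediator complex, from 8.87 to 0.437 FPKM (20.3-fold), myoglobin (mb) from 5.23 to 0.515 FPKM, the otolith matrix gene otomp from 3.35 to 0.427 FPKM, the G protein regulator rgs5b from 4.09 to 0.636 FPKM, and a histone H2A gene annotated as HIST2H2AB (20 of 30) from 12.9 to 1.69 FPKM, a member of a family of near-identical copies. IAPP, the islet amyloid polypeptide, was at 1.12 FPKM in wild-type and listed at 0 in the knockdown. Among those that rose were the collagenase mmp13a from 2.55 to 13.4 FPKM, the thyrotropin-releasing hormone precursor trh from 1.5 to 5.71 FPKM, and fsta, a follistatin that binds activin, from 6.68 to 19.2 FPKM. The rows for 5_8S_rRNA, at 61.6 and 336 FPKM, and the small nucleolar RNA SNORD14, listed at 0 and at 104 FPKM, also carried a call. Cdk19, vmhc, tie2 and SNORD14 share their locus with another row of the table, so reads of overlapping genes can enter their values.

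**Figure D3:**
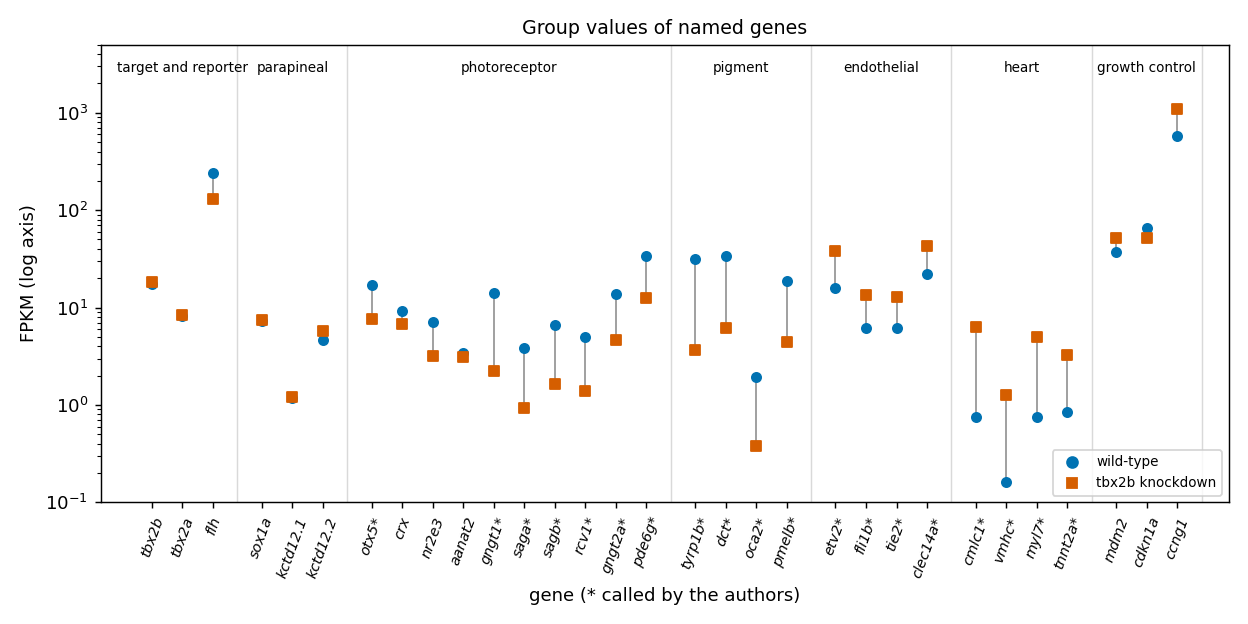
The authors' group values (FPKM, log axis) of named genes are shown for wild-type (circles) and tbx2b knockdown (squares), grouped by what the genes do; stars mark genes called by the authors. Tbx2b lies at 17.4 and 18.3 FPKM, photoreceptor and pigment genes called by the authors lie lower in the knockdown, and the endothelial and heart genes shown lie higher.

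The calls rest on the authors' q of at most 0.0457. Unadjusted p was under 0.05 for 1048 of 18954 tested genes, 336 higher and 712 lower. That is close to the share of 0.05 that p values give without any difference. The share does not describe the calls, since 54 genes have the smallest p of 5e-05, more than the same reckoning would give. Whether the test treated paired technical replicates as independent is not given in the sources used here, and the wild-type embryos were uninjected, so the injection itself and the loss of Tbx2b cannot be separated by this comparison.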

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

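No paired analysis was possible because the authors' table holds group values and its columns carry no replicate number; for the same reason the alternatives that leave out libraries or use the sort batch were not run. At a deposited q under 0.01 there were 0 higher and 0 lower genes, which follows from the smallest possible q of 0.0176. Requiring in addition an absolute log2 fold of 1 on log2(FPKM + 1) left 13 higher genes; the pseudocount lowers every fold, and clec14a, at a log2 fold of 0.96, misses the threshold without it. Under the other settings counts were within 1.5 times the original, from 19 to 20 higher and from 53 to 64 lower. Of the fixed list medians recomputed with 4 alternatives, 88 kept their side of the limits, 2 left the range of lists standing apart (1 of them the list not reported here), 1 entered it and 1 changed direction while entering it. The erythroid median moved from -2.31 to -1.25 with members of 1 FPKM or more and to -0.76 on log2(FPKM + 1), at the 0.00 percentile in each. With members of 1 FPKM or more, the myeloid list fell to 0.05 and the hatching gland list turned to -0.30 at the 0.32 percentile; the cause was not tested. With called members left out, a setting chosen after seeing the data, the heart list fell to 0.11 at the 88.5 percentile and the histone list to -0.10 at the 18.0 percentile; the other lists kept their side. Depth is unknown, so low genes such as vmhc carry an error that cannot be given.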

Other observations

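The lists, tests and neighbour counts in this part were chosen after the calls were seen, except the test of a developmental delay, whose bound was set when 2 of the 26 neuronal genes had been looked at. Genes of retinal pigment epithelium and the visual cycle, which regenerate the visual chromophore, had a median log2 fold change of -0.81 at the 0.00 percentile (-0.33 at the 0.34 percentile without the called members, and -0.51 on log2(FPKM + 1)), and 5 of 18 fell: rgra from 18.3 to 4.91 FPKM, rdh5 from 16.3 to 5.25 FPKM, rpe65a from 43.7 to 21.2 FPKM, rlbp1b and rbp4l. All 14 melanin synthesis genes lay below 0, with a median of -0.99 at the 0.00 percentile, and 4 of them fell. Immediate early and cytokine feedback genes had a median of -0.61 at the 0.00 percentile (-0.38 without the called members), with 29 of 30 below 0 and 8 fallen, among them socs1 from 18.0 to 7.03 FPKM, npas4a from 1.41 to 0.349 FPKM and txnipb from 27.1 to 7.35 FPKM. Of 12 linker and core histone genes 3 fell, namely hist2h2l from 271 to 94.7 FPKM, h1fx from 86.8 to 36.1 FPKM and h1f0 from 649.7 to 307 FPKM, and the median was -0.32 at the 0.10 percentile, but -0.10 at the 18.0 percentile without the called members. Heart muscle genes had a median of 0.57 at the 99.99 percentile, and 4 of 14 rose; without these 4 the median was 0.11 at the 88.5 percentile, so the shift rests on the genes that prompted the list. Ribosomal protein genes had a median of -0.28, with all 77 below 0 and none called; rescaled to TPM the median was -0.18 and all 77 stayed below 0. Of the 71 other tested genes with a mean of 1000 FPKM or more, 52 lay below 0, with a median of -0.13.

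Some called genes lay close together on the chromosomes. Of the 83 called genes 13 had another called gene within 100 kb, against a median of 2 and a highest value of 12 in 1000 random sets. The neighbours include etv2 and fli1b on chromosome 16, the alpha globins on chromosome 3, the doublesex-related genes dmrt2a and dmrt3a on chromosome 5, and prl with an adjoining clone locus on chromosome 3. They also include HIST2H2AB (20 of 30) with a row that carries no symbol on chromosome 7, and hist2h2l with SNORD14 on chromosome 10, which went in opposite directions. Tandem copies such as the globins can share reads, and the excess over the random sets was not tested without them. Dmrt3a fell from 22.3 to 9.30 FPKM and the prolactin gene prl fell from 34.2 to 8.51 FPKM.

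Photoreceptor, pigment and visual cycle genes were lower in the knockdown. A smaller share of pineal cells in the sort would raise the markers of other cell types. The endothelial median exceeded the erythroid median by 3.08 (log2), where the half-widths of their random ranges sum to 0.354. On log2(FPKM + 1) these medians were 0.69 and -0.76. These lists were the most extreme and were paired after their values were seen, so the contrast cannot decide the question. Muscle, epidermis, myeloid and notochord medians, at 0.39, 0.32, 0.17 and 0.16, stood apart higher, and the neural crest and lens medians lower. Flh, whose regulatory sequence drives the reporter, was at 238 and 129 FPKM. It was not called, but was lower adjusted over the epithalamus list alone. A general developmental delay would lower neuronal differentiation genes, and the median of the neuronal list was 0.064 (half-width of random lists 0.124). This list also holds early neuronal genes, and elavl3 was already at 123 FPKM in wild-type. A delay need not lower the list's median, so the value cannot decide the question. A smaller share of pineal cells and a developmental delay stay open. So do a loss of pigmented or photoreceptor cells, a lower expression in each cell and fewer cells from the eye, which were not tested. The reduction of Tbx2b itself stays open too and was not tested. A sort on the reporter should remove eye cells unless they fluoresce, though the lens crystallin crybb1 was at 17.5 and 9.55 FPKM.

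Endothelial genes and 4 heart muscle genes were higher in the knockdown. More cells of every blood and vascular lineage would raise erythroid markers too, and their median was -2.31. That value had been seen when the test was written. Members went both ways, with 10 below 0, the globins among them, and 4 above 0, among them tal1, which rose. The median therefore cannot decide the question. More vascular cells in the sort would raise most endothelial markers together, and their median was 0.77. The most abundant, clec14a and etv2, were at 42.7 and 38.4 FPKM in the knockdown. Without the called members the median was 0.73 at the 100 percentile, so the shift does not rest on them. The prediction was written after the called genes had been seen and restates the pattern, so it gives no separate support for more vascular cells. Sorting on the reporter should remove such cells unless they fluoresce. RNA of other cell types was nonetheless present, the epidermis marker cyt1l being at 64.8 and 94.4 FPKM. Group values do not show whether both RNA samples of a group share the change, and higher expression in the same cells may give the same values, as may an effect of Tbx2b.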
